A study of Mus musculus with 5 samples.

How the data were processed

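Per the labels' protocols, the urothelium was dissected off the muscularis propria, frozen and pulverised, total RNA was taken with TRI-Reagent, and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.11.1 and DESeq2 were used with genome build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene on the opposite strand are uncertain. The deposited values used here were raw gene counts, 1 column per library. The design text describes separate mice, so each library was taken as 1 mouse, and the age was 10 weeks in all 5. Nothing was realigned.

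The 24970 genes were kept apart from 5 summary entries of the counting program (reads in no gene, ambiguous, low quality, not aligned and not uniquely aligned), which were left out of library sizes and tests. Genes held 49.3%, 54.9%, 56.2%, 56.3% and 60.6% of all tallied reads in WT 1, WT 2, KO 1, KO 2 and KO 3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14779, and libraries were scaled with TMM factors of 0.988, 1.03, 0.978, 0.986 and 1.02. CPM values are counts scaled to a common library size with these factors. The test was the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05, and the common biological coefficient of variation was 0.109. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Replicate numbers carry no order, and no sample column with further information was left unused.

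Gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule took the measured Notch genes, up to 4 members with the smallest p of each other list plus 13 urothelial and mesenchymal genes set in advance, the 10 highest and 10 lowest changed genes with no overlap between genotypes, and the 5 smallest p in each direction, and other list members named in the results were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Genes with no count in 1 group are given as a bound at a floor of 3 counts over the group. Ratios of genes with 1 to 3 counts in a group carry 95% intervals that cover counting error alone, not differences between mice. Between replicates, counts varied 9.70 to 38.4 times as much as counting error alone gives (chi-square per degree of freedom). The most abundant entries, such as the precursor ribosomal RNA Rn45s, weigh most in this sum over all genes.

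The test was run on simulated data of 14622 genes with 50 genes altered at each fold. It recovered 34% at 1.5-fold, 76% at 2-fold, 98% at 4-fold and 100% at 8-fold, so many changes under 2-fold were missed there with 2 against 3 mice. In the data 2907 of 14779 genes passed, which makes the adjustment less strict than in the simulation. These shares need not hold for the data. Of 170 calls, 16 (9.41%) were false, more than the 5% aimed for. A planted list was called (adjusted p = 1.70e-14) and 0 of 40 random lists were, which does not test lists whose members vary together between mice.

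Positions come from GENCODE vM21 on GRCm38, matched by symbol for 24491 of 24970 genes (98.1%, 69 of them by synonym). Eyelinc18 was not matched and has no position here. The alternatives were other scaling factors, looser and stricter filters, a robust fit, DESeq2, limma-voom, a block for replicate number, leaving out each library, and leaving out ribosomal and nuclear RNA entries, the last chosen after the data were seen.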

Results

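RNA was sequenced from the urothelium, the epithelial lining of the bladder, of 5 mice aged 10 weeks. The animals were 2 wild types (WT 1 and WT 2) and 3 Nicastrin knockouts (KO 1 to KO 3), with 1 library per mouse. The knockouts carried Krt5-CreERT2, an inducible Cre recombinase driven by the basal cell keratin gene Krt5, together with floxed alleles of Ncstn. Nicastrin, the product of Ncstn, is a subunit of gamma-secretase, the membrane protease that releases the signalling part of Notch receptors. The comparison asks how the urothelium changes when this step of Notch signalling is removed from cells that express Krt5 and from their descendants. The labels name a strain for the wild types but only a genotype for the knockouts. How and when the Cre was induced is not given in the sources used here. The comparison therefore cannot separate loss of Ncstn from any difference in strain background, in the Cre or in its induction. Counts assigned to genes came to 19384171 in WT 1, 13936790 in WT 2, 27188499 in KO 1, 16872894 in KO 2 and 12608836 in KO 3, and 16912 to 18796 genes had at least 1 count. The precursor ribosomal RNA Rn45s took 7.84% and 3.23% of gene counts in WT 1 and WT 2 and 1.53%, 1.14% and 0.608% in KO 1, KO 2 and KO 3. The nuclear RNA Malat1 took 0.390% and 0.281% in the wild types and 0.0658%, 0.0736% and 0.0779% in the knockouts.

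Of 14 Notch target genes, 4 fell and 2 rose in the knockouts. Hey1 and Heyl were 3.09-fold and 2.91-fold lower, the targets Myc and Lfng were 2.56-fold and 2.31-fold higher, and Hes1 did not differ past the test. The basal keratin Krt14 was 32.9-fold higher and Upk2, which encodes a plaque protein of umbrella cells, was 1.83-fold higher. Among gene lists, 25 of 31 fibrillar matrix genes, 23 of 32 interferon response genes and 12 of 27 proliferation genes fell, whereas 11 of 19 tight junction genes and 8 of 18 umbrella cell genes rose. In all, 2907 of 14779 tested genes (19.7%) changed in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05, with 1424 higher and 1483 lower in the knockouts. Of these, 304 were over 2-fold higher and 602 were over 2-fold lower, and 5145 genes had an unadjusted p under 0.05. The knockout and wild-type CPM values did not overlap in 51.0% of tested genes, where chance gives 20%. Spearman correlations across genes, which are not independent replicates, were 0.990 to 0.995 within a genotype and 0.971 to 0.982 between genotypes. The number of changed genes was 715 without WT 1, 1429 without WT 2, 1747 without KO 1, 1901 without KO 2 and 3989 without KO 3, and no gene called in the full set changed sign.

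Gene lists were fixed before the data were examined and tested with limma camera at a preset correlation of 0.01, adjusted over 43 lists. This test called 20 lists, 11 higher and 9 lower in the knockouts. None of these 20 calls held when the correlation between genes was estimated from the data (3 lists had an unadjusted p under 0.05, smallest adjusted p = 0.448). That setting tests on the few degrees of freedom left by the libraries, so it had little power here. For the list of hedgehog, Wnt and BMP genes, the estimated correlation was -0.014, below the preset 0.01. The unadjusted camera p of that list still went from 7.90e-06 to 0.0167. The losses therefore do not show that correlated genes produced the calls. Fry called 11 lists, of which 9 were among these 20. The others were the Notch target list and the B and plasma cell list. Counts given as adjusted over the list alone use the same edgeR p values with the adjustment limited to that list. Genes such as Plaur, Tbx3, Thbs1, Clec3b, Foxm1, Lamb1, Lamb3, Wnt7b, Il1r2 and Vcam1, named below as members that moved against or beside the rest of their list, were chosen after their values were seen.

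**Figure D1:**
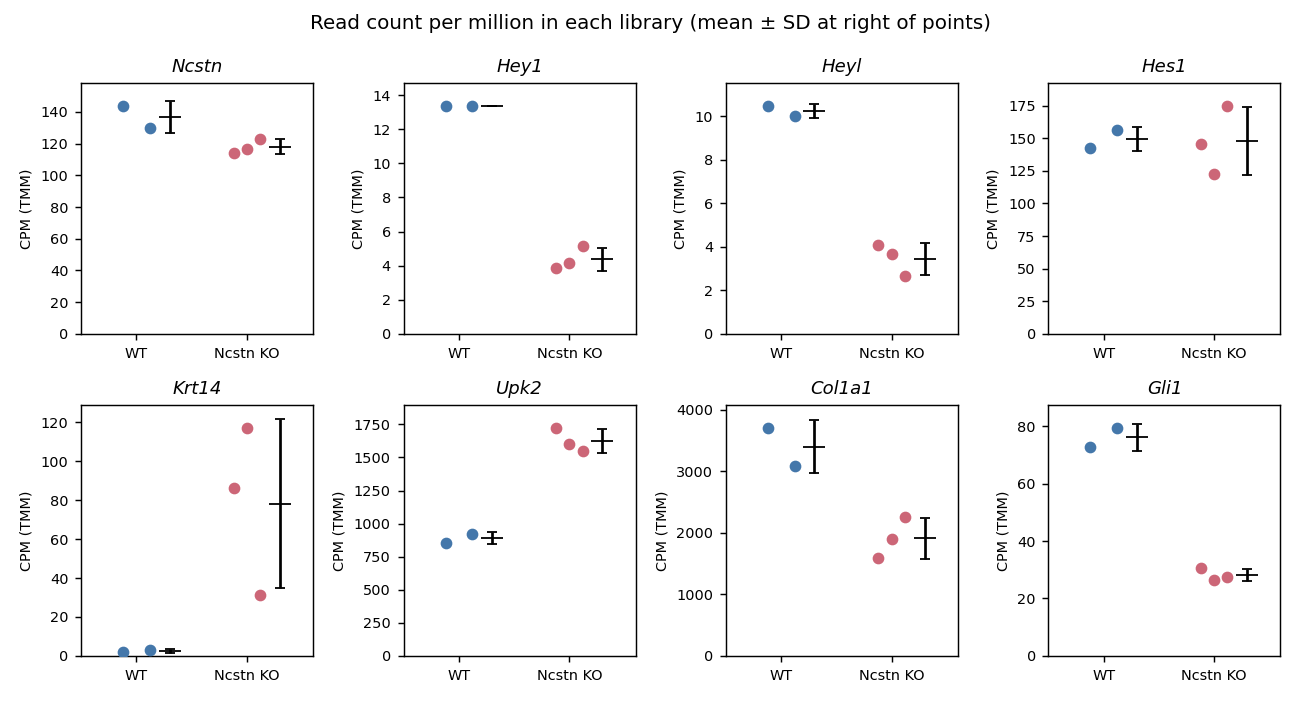
Normalised CPM (y axis, linear from 0) of 8 genes in each of the 2 wild-type (blue) and 3 knockout (red) libraries, with the mean ± SD beside the points. Hey1, Heyl, Col1a1 and Gli1 lay lower and Krt14 and Upk2 higher in all 3 knockouts, whereas Hes1 overlapped and Ncstn (log2 fold change -0.21) did not pass the test.

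Ncstn itself lies on chromosome 1 from 172066013 to 172082795 (GRCm38). It was measured at 144 and 130 CPM in WT 1 and WT 2 and at 114, 117 and 123 CPM in KO 1, KO 2 and KO 3. The log2 fold change of Ncstn was -0.21 ± 0.09 (SE) and did not pass the test (edgeR adjusted p = 0.133), although all 3 knockouts lay below both wild types. These counts cover the entire gene and all dissected cells, so reads from exons outside the floxed part and from cells that never expressed Krt5 are included, and the level does not check the deletion. The gamma-secretase list of 7 measured genes had a median of 0.15, a mean of -0.06 and an upward test direction (camera adjusted p = 0.785). Among 8 Notch receptors and ligands, Notch1 fell from 407 ± 60.8 CPM (SD, n = 2) to 261 ± 38.9 CPM (SD, n = 3; edgeR adjusted p = 0.0115) and the ligand gene Dll1 rose 2.08-fold (edgeR adjusted p = 0.00979). The other 6 did not pass, 1 was higher and 1 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.693).

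Of 14 Notch target genes, 4 fell, 2 rose and 8 did not pass, and adjusted over the list alone 5 were lower and 2 higher. The transcriptional repressor gene Hey1 fell from 13.4 ± 0.0084 CPM (SD, n = 2) to 4.38 ± 0.679 CPM (SD, n = 3; edgeR adjusted p = 0.000389), and its relative Heyl fell from 10.3 ± 0.326 to 3.46 ± 0.732 CPM (edgeR adjusted p = 0.00116). Hey2 had a log2 fold change of -0.93 (edgeR adjusted p = 0.0713), and Hes1 was at 149 ± 9.31 and 148 ± 26.2 CPM (edgeR adjusted p = 0.947). Nrarp was at 191 ± 0.576 and 234 ± 30.4 CPM and did not pass (edgeR adjusted p = 0.102). The cyclin gene Ccnd1 and the inhibitor of DNA binding gene Id3 fell by 0.62 and 0.42 on the log2 scale. Myc, which encodes a growth-promoting transcription factor, rose 2.56-fold (edgeR adjusted p = 9.66e-05), and Lfng, which encodes a glycosyltransferase acting on Notch receptors, rose 2.31-fold. The list as a set was not called by camera (adjusted p = 0.506, median log2 fold change -0.15) and was called lower by fry (adjusted p = 0.00964). Without WT 1, the calls of Notch1 (edgeR adjusted p = 0.133), Dll1 (0.126), Lfng (0.0553) and Id3 (0.0602) were lost. Those of Dll1 (edgeR adjusted p = 0.0611) and Id3 (0.117) were lost without WT 2, and that of Id3 (0.0717) without KO 1.

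Uroplakins are the plaque proteins of umbrella cells, the superficial layer that seals the bladder against urine. Of 18 umbrella cell genes, 8 rose, 1 fell and 9 did not pass, and adjusted over the list alone 10 were higher and 1 lower. Upk2 rose from 890 ± 47.5 CPM (SD, n = 2) to 1626 ± 89.2 CPM (SD, n = 3; edgeR adjusted p = 0.00119), Upk1a rose 1.57-fold and Upk3a rose 1.54-fold. Snx31, which encodes a uroplakin-sorting protein, rose 1.66-fold (edgeR adjusted p = 0.00155), and the member that fell was Plaur, which encodes the urokinase receptor (log2 fold change -0.75). Krt20, a keratin of mature umbrella cells, did not pass (log2 fold change 0.25, edgeR adjusted p = 0.197). The list median was 0.42 and the list was called higher (camera adjusted p = 0.000330), with adjusted p = 0.627 with an estimated correlation. In the same libraries the fibroblast, matrix and endothelial lists had medians of -0.56, -0.86 and -0.37. Among 15 transcription factors of urothelial differentiation, 4 rose, 1 fell and 10 did not pass, with 5 higher and 1 lower adjusted over the list alone. Grhl3, a factor of barrier formation, rose 2.13-fold (edgeR adjusted p = 0.000125), Klf4 rose 1.88-fold, Elf3 rose 1.47-fold and Gata3 rose 1.28-fold, while Tbx3 fell by 0.30 on the log2 scale. Pparg and Foxa1 had log2 fold changes of 0.41 and 0.22 and did not pass (edgeR adjusted p = 0.0707 and 0.181). The differentiation factors were called higher as a list (median 0.22, camera adjusted p = 0.0138), with adjusted p = 0.501 with an estimated correlation.

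The 16 measured basal cell genes split, with 4 higher, 3 lower and 9 not past the test, and 5 higher and 3 lower adjusted over the list alone. Krt14, a keratin of basal cells, rose from 2.46 ± 0.962 CPM (SD, n = 2) to 78.3 ± 43.6 CPM (SD, n = 3; edgeR adjusted p = 0.000469), with 86.4, 117 and 31.2 CPM in KO 1, KO 2 and KO 3. The P-cadherin gene Cdh3 rose 2.32-fold, Ngfr rose 3.09-fold and the integrin gene Itga3 rose 1.91-fold, while Lamb3, Itga6 and Cd44 fell by 0.37, 0.34 and 0.35 on the log2 scale. Krt5 was at 1491 ± 266 and 1861 ± 343 CPM and Trp63, a transcription factor of basal cells, at 361 ± 50.8 and 374 ± 42.0 CPM, and neither passed (edgeR adjusted p = 0.226 and 0.815). The basal list had a median of 0.20 and was not called (camera adjusted p = 0.159), although it was without KO 3 (camera adjusted p = 0.000153). Of 13 squamous genes, the cornified envelope gene Sprr1a rose 1.94-fold (edgeR adjusted p = 0.00119), the keratin gene Krt4 fell 2.60-fold and 11 did not pass, with the same counts of 1 and 1 adjusted over the list alone. The squamous list had a median of -0.09, a mean of 0.04 and an upward test direction (camera adjusted p = 0.994).

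Without WT 1, 2 umbrella cell genes, 2 differentiation factors and 2 basal genes rose, and the calls of Upk1a (edgeR adjusted p = 0.0545), Upk3a (0.0887), Elf3 (0.0681), Gata3 (0.0832), Ngfr (0.135), Itga3 (0.117) and Krt4 (0.123) were lost. The umbrella cell genes that rose numbered 5 without KO 1 and 4 without KO 2, the basal genes 2 without WT 2 and 8 without KO 3, the differentiation list was not called without WT 2 (camera adjusted p = 0.0834), and Gata3 was lost without any of WT 2, KO 1 and KO 2 (edgeR adjusted p = 0.193, 0.127 and 0.124). Tbx3 did not pass without WT 1, WT 2, KO 1 or KO 2 (edgeR adjusted p = 0.247, 0.0673, 0.154 and 0.109), nor Plaur without WT 1 or WT 2 (0.0752 and 0.1096). Lamb3, Itga6 and Cd44 did not pass without WT 1 (edgeR adjusted p = 0.0676, 0.212 and 0.197) or KO 1 (0.0682, 0.0803 and 0.0721), nor Lamb3 and Cd44 without WT 2 (0.0725 and 0.0851), nor Itga6 and Cd44 without KO 2 (0.0741 and 0.126). With all libraries, Krt4 did not pass in a robust fit (edgeR adjusted p = 0.194) or in DESeq2 (adjusted p = 0.0918), Itga3 not in a robust fit (edgeR adjusted p = 0.0550), and Gata3 not with upper-quartile scaling or a filter at 5 CPM (0.0591 and 0.0661). Ngfr, Itga3 and Krt4 were also lost without WT 2 (edgeR adjusted p = 0.0801, 0.105 and 0.0925), and Upk3a without KO 2 (0.0534).

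Tight junction components seal the space between epithelial cells. Of 19 such genes measured, 11 rose, none fell and 8 did not pass, and adjusted over the list alone 12 were higher. The claudin genes Cldn23 and Cldn1 rose 1.87-fold and 1.89-fold (edgeR adjusted p = 0.000289 and 0.000571), the polarity gene Pard6b rose 2.05-fold and Tjp3 rose 1.52-fold. As a list, tight junction genes were called higher (median 0.39, camera adjusted p = 4.57e-06), with adjusted p = 0.501 with an estimated correlation, in the same libraries in which 12 of 18 fibroblast markers fell. Of 12 desmosome genes, 5 rose, 2 fell and 5 did not pass, with 5 and 2 adjusted over the list alone. Evpl, which encodes the cornified envelope protein envoplakin, rose 1.55-fold (edgeR adjusted p = 0.00460) and Jup, which encodes plakoglobin, rose 1.42-fold, while Pkp1 and Dsc2 fell by 0.57 and 0.45 on the log2 scale. The desmosome list was not called (median 0.32, camera adjusted p = 0.134). Among 12 adherens junction genes, Cdh3 rose and 11 did not pass, with 1 adjusted over the list alone (median 0.16, camera adjusted p = 0.0599). The E-cadherin gene Cdh1 was at 587 ± 19.9 and 642 ± 20.1 CPM (edgeR adjusted p = 0.399).

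Hemidesmosomes and the basement membrane anchor the epithelium. Of 23 such genes measured, 8 fell, 1 rose and 14 did not pass, and adjusted over the list alone 10 were lower and 2 higher. The laminin gene Lama2 fell 2.02-fold (edgeR adjusted p = 0.000908), the nidogen gene Nid1 fell 1.81-fold, the perlecan gene Hspg2 fell 2.07-fold and Col4a5 fell 1.46-fold, while Lamb1 rose by 0.50 on the log2 scale. Basement membrane genes were called lower as a list (median -0.34, camera adjusted p = 0.0119), with adjusted p = 0.645 with an estimated correlation. That call was lost without WT 1 and without KO 3 (camera adjusted p = 0.0785 and 0.116), the members that fell numbered 2 without WT 1 and 4 without KO 1, and Hspg2 and Col4a5 did not pass without WT 1 (edgeR adjusted p = 0.127 and 0.0749). Tight junction genes that rose numbered 4 without WT 1, 4 without WT 2, 7 without KO 1 and 6 without KO 2, and desmosome genes 2, 1, 2 and 2, with 3 in all libraries under upper-quartile scaling. Tjp3 (edgeR adjusted p = 0.0520) and Pkp1 (0.184) did not pass without WT 1, Jup (0.0630) and Pkp1 (0.0675) not without WT 2, and Pkp1 (0.0714) not without KO 1. Dsc2 did not pass without WT 1, WT 2 or KO 2 (edgeR adjusted p = 0.361, 0.0630 and 0.124), nor Lamb1 without WT 1, WT 2, KO 1 or KO 2 (0.109, 0.199, 0.0848 and 0.113), while the adherens junction list was called without WT 1 (camera adjusted p = 0.0140).

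Fibrillar matrix genes, which encode the collagens and linked proteins of connective tissue, were the list with the smallest camera p. Of 31 measured, 25 fell, 1 rose and 5 did not pass, and adjusted over the list alone 28 were lower and 1 higher. The collagen gene Col15a1 fell from 101 ± 19.2 CPM (SD, n = 2) to 24.96 ± 1.31 CPM (SD, n = 3; edgeR adjusted p = 1.56e-05). The proteoglycan genes Lum and Vcan fell 3.01-fold and 2.57-fold, the microfibril gene Mfap4 fell 5.95-fold and Col1a1 fell 1.78-fold (edgeR adjusted p = 0.00713), while the thrombospondin gene Thbs1 rose 2.87-fold. Matrix genes as a list were called lower (median -0.86, camera adjusted p = 4.43e-26), with adjusted p = 0.448 with an estimated correlation. Without WT 1, 16 members fell and Col1a1 did not pass (edgeR adjusted p = 0.0740).

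Fibroblasts are the cells that make this matrix. Of 18 fibroblast markers measured, 12 fell, 1 rose and 5 did not pass, and adjusted over the list alone 12 were lower and 3 higher. Serpinf1 fell 2.31-fold (edgeR adjusted p = 0.000496), Pi16 fell 1.91-fold and Cd34 fell 1.83-fold, while Clec3b rose by 0.67 on the log2 scale. Of these 18 markers, Col1a1, Col1a2, Col3a1, Dcn, Lum, Fbln1 and Mfap5 also belong to the matrix list. The fibroblast list was called lower (median -0.56, camera adjusted p = 4.57e-06), with adjusted p = 0.501 with an estimated correlation. Of 15 mesenchymal genes, 6 fell, none rose and 9 did not pass, with 9 lower adjusted over the list alone. They included the filament gene Vim, from 553 ± 8.27 to 331 ± 23.9 CPM (edgeR adjusted p = 0.00126), Sparc, which fell 2.29-fold, and the transcription factor genes Zeb2 and Tcf4, which fell 1.67-fold and 1.66-fold. The mesenchymal list was called lower (median -0.65, camera adjusted p = 4.85e-05), with adjusted p = 0.448 with an estimated correlation.

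Endothelial markers fell in 5 of 14 cases, with 1 higher and 8 not past the test, and adjusted over the list alone 8 were lower and 1 higher. The receptor genes Kdr and Flt1 fell 2.40-fold and 1.61-fold (edgeR adjusted p = 9.73e-05 and 0.00369) and Sox17 fell 2.22-fold, while Lyve1, a marker of lymphatic vessels and some macrophages, rose 5.45-fold. Endothelial markers as a list were called lower (median -0.37, camera adjusted p = 0.000944), with adjusted p = 0.501 with an estimated correlation. Of 17 smooth muscle markers, 3 fell, none rose and 14 did not pass, with 3 lower adjusted over the list alone. These were Smtn, Pgm5 and Ckb, which fell by 0.33, 0.56 and 0.47 on the log2 scale, and the list had a median of -0.04, a mean of 0.05 and a downward test direction (camera adjusted p = 0.693). Acta2 was at 109 ± 25.3 and 158 ± 36.9 CPM (edgeR adjusted p = 0.0775). Clec3b did not pass without WT 1 or KO 2 (edgeR adjusted p = 0.208 and 0.0601). Fibroblast markers that fell numbered 5 without WT 1, endothelial markers 3, and without WT 1 the calls of Flt1 (edgeR adjusted p = 0.0624), Smtn (0.143), Pgm5 (0.373) and Ckb (0.140) were lost. Smtn and Ckb did not pass without WT 2 (0.0759 and 0.146), KO 1 (0.0996 and 0.114) or KO 2 (0.0633 and 0.0927) either, nor did Ckb in DESeq2 with all libraries (adjusted p = 0.0559) or Pgm5 without KO 1 (0.113) or KO 2 (0.0766).

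Of 20 matrix protease and inhibitor genes, 5 rose, 1 fell and 14 did not pass, with 5 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.208). Adamts1 rose 1.90-fold (edgeR adjusted p = 0.00136), and Mmp7, which had 1 wild-type count, had a ratio of 50.2 (95% counting interval 8.77 to 2006). Among 15 genes of the TGF-beta response, 3 rose, 3 fell and 9 did not pass, with 3 and 4 adjusted over the list alone. The matricellular protein genes Ctgf and Cyr61 rose 5.53-fold and 7.90-fold (edgeR adjusted p = 5.00e-05 and 0.00411), although Cyr61 did not pass in a robust fit (edgeR adjusted p = 0.122), while Tgfb3 and Skil fell by 0.67 and 0.51 on the log2 scale. Cyr61 was at 5.17 CPM in WT 1 and 27.1 CPM in WT 2, so the size of its rise depends on which wild type is used. The TGF-beta list had a median of -0.21, a mean of 0.16 and an upward test direction (camera adjusted p = 0.994). Without WT 1 the calls of Mmp7, Tgfb3 and Skil were lost (edgeR adjusted p = 0.156, 0.0545 and 0.0772), that of Mmp7 also without WT 2 (0.0665), and the protease genes that rose numbered 1 without any of WT 1, WT 2 and KO 1 and 3 without KO 2.

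**Figure D2:**
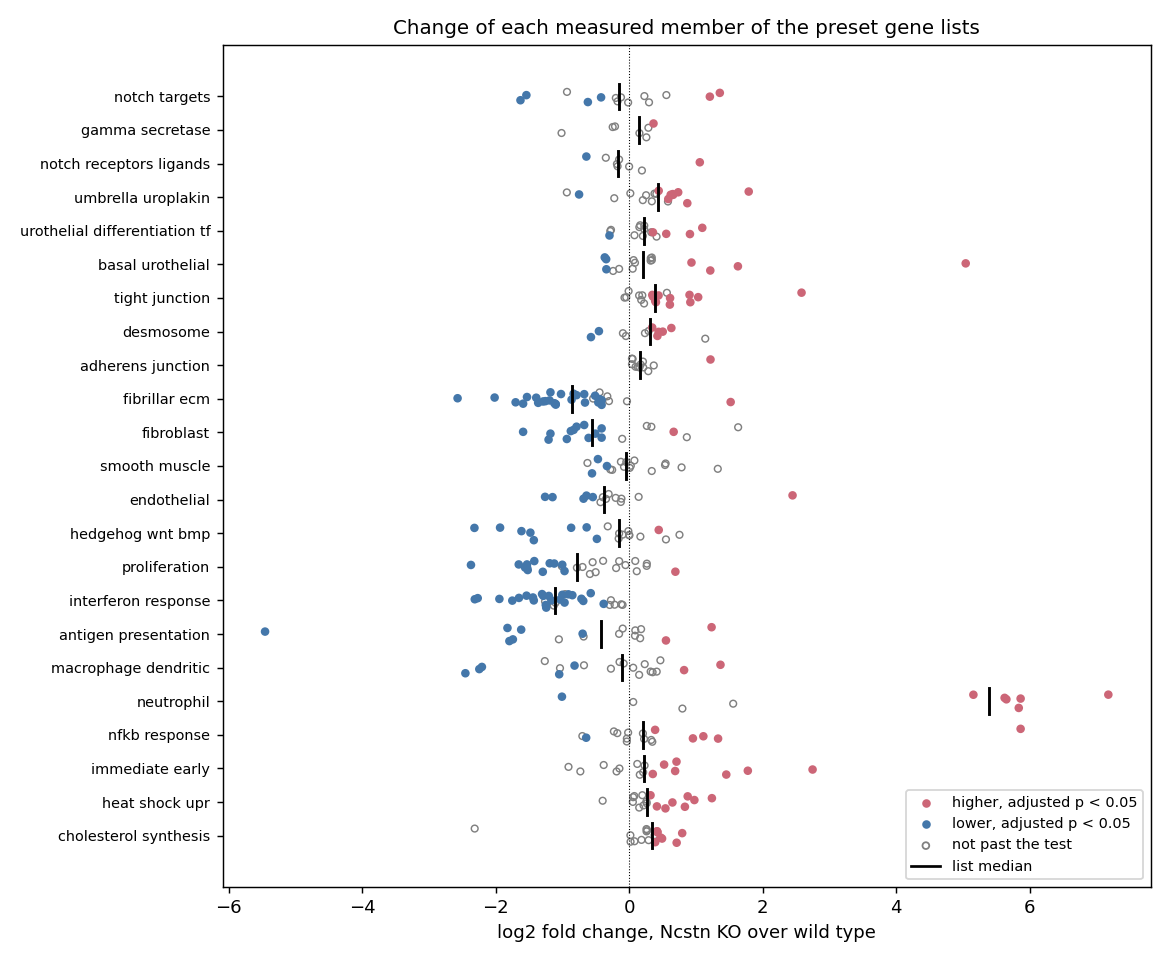
Log2 fold change, knockout over wild type (x axis), of each measured member of 23 gene lists fixed before the data were examined (y axis), with filled points for genes past the edgeR test, open points for the others and a black bar at the list median. The medians of fibrillar matrix (-0.86), proliferation (-0.78) and interferon response (-1.12) lay to the left and that of neutrophil genes (5.39) to the right.

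The hedgehog receptor gene Ptch1 fell from 235 ± 31.6 CPM (SD, n = 2) to 84.4 ± 5.04 CPM (SD, n = 3; edgeR adjusted p = 2.98e-05), the transcription factor gene Gli1 fell 2.69-fold (edgeR adjusted p = 3.36e-05) and Hhip, which encodes a secreted hedgehog antagonist, fell 3.06-fold. Shh, the ligand gene, was at 272 ± 9.51 and 245 ± 31.4 CPM (edgeR adjusted p = 0.392). Of 19 hedgehog, Wnt and BMP genes measured, 8 fell, 1 rose (Wnt7b, log2 fold change 0.44) and 10 did not pass, and adjusted over the list alone 8 were lower and 2 higher. As a list, these pathway genes were called lower (median -0.16, mean -0.51, camera adjusted p = 4.85e-05), with adjusted p = 0.448 with an estimated correlation. In the same libraries 12 of 18 fibroblast markers and 25 of 31 fibrillar matrix genes fell and 1 of each rose (medians -0.56 and -0.86). Whether the fall of Ptch1, Gli1 and Hhip is separate from that fall was not tested. Of 27 proliferation genes, 12 fell, 1 rose and 14 did not pass, and adjusted over the list alone 13 were lower and 1 higher. The replication helicase gene Mcm6 fell 5.17-fold (edgeR adjusted p = 7.62e-06), the cycling cell marker Mki67 fell 3.15-fold, Top2a fell 2.45-fold and Kif11 fell 2.95-fold, while Foxm1, a cell cycle transcription factor gene, rose by 0.69 on the log2 scale. The proliferation list was called lower (median -0.78, camera adjusted p = 4.57e-06), with adjusted p = 0.501 with an estimated correlation. Proliferation genes that fell numbered 3 without WT 1 and 5 without WT 2, Kif11 did not pass without WT 1 (edgeR adjusted p = 0.0625), and 5 hedgehog, Wnt and BMP genes fell without WT 2. Without WT 1, WT 2, KO 1 or KO 2, neither Foxm1 (edgeR adjusted p = 0.199, 0.0562, 0.0645 and 0.0512) nor Wnt7b (0.106, 0.0696, 0.0556 and 0.0529) passed.

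Interferon response genes are switched on in antiviral defence. Of 32 measured, 23 fell, none rose and 9 did not pass, and adjusted over the list alone 28 were lower. The antiviral gene Ifit3 fell 4.82-fold (edgeR adjusted p = 0.000858), Ifi27l2a fell 2.91-fold, the guanylate-binding protein gene Gbp3 fell 2.44-fold and Oasl2 fell 2.37-fold. Camera called the interferon list lower (median -1.12, camera adjusted p = 1.81e-15), with adjusted p = 0.501 with an estimated correlation. Of 16 antigen presentation genes, 6 fell, 2 rose and 8 did not pass, with 6 and 2 adjusted over the list alone. The class II gene H2-Eb1 fell from 86.4 ± 12.9 CPM (SD, n = 2) to 2.09 ± 0.764 CPM (SD, n = 3; edgeR adjusted p = 7.39e-07), and of the class I genes H2-K1 fell 1.62-fold while H2-D1 rose 2.35-fold. Camera called the antigen presentation list lower (median -0.42, camera adjusted p = 0.00442), with adjusted p = 0.645 with an estimated correlation. Members such as H2-Eb1, H2-K1, H2-D1 and H2-DMb1 lie in the chromosome 17 interval described below, where 38.2% of tested genes changed against 19.5% elsewhere. The knockouts differed among themselves here, with H2-Aa at 14.6, 18.7 and 63.9 CPM in KO 1, KO 2 and KO 3. Interferon genes that fell numbered 15 without WT 1 and 11 without WT 2, antigen presentation genes 3 and 2, and a robust fit of all libraries gave 3 antigen presentation genes lower and 1 higher. Without WT 2 the antigen presentation list was not called (camera adjusted p = 0.0589).

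Most of the neutrophil genes that rose had fewer than 10 counts over both wild types. Of 10 measured, 6 rose, 1 fell (Il1r2, log2 fold change -1.01) and 3 did not pass, and adjusted over the list alone 8 were higher and 1 lower. S100a8 had 2 wild-type and 560 knockout counts, a ratio of 167 (95% counting interval 46.1 to 1385), and S100a9 rose from 0.305 ± 0.357 CPM (SD, n = 2) to 15.8 ± 13.9 CPM (SD, n = 3; edgeR adjusted p = 0.00477). Lcn2, an iron-sequestering protein that epithelial cells also make, rose from 0.131 ± 0.111 to 7.29 ± 4.93 CPM (edgeR adjusted p = 0.00204). Mmp8 had 1 wild-type count and a ratio of 61.6 (95% counting interval 10.8 to 2455). Camera called the neutrophil list higher (median 5.39, camera adjusted p = 0.000435), with adjusted p = 0.629 with an estimated correlation. S100a8, Mmp8, Retnlg and Ngp each had 1 to 3 wild-type counts, so the median rests on imprecise ratios. Without WT 1, 1 neutrophil gene rose, and S100a9 (edgeR adjusted p = 0.0883, and with all libraries 0.117 in a robust fit and 0.0622 in limma-voom), Lcn2 (0.0545) and Mmp8 (0.0696) did not pass. Without WT 2, 3 rose and Mmp8 (0.0587) did not pass, and without KO 1, 3 rose. Il1r2 did not pass without WT 1 or WT 2 (edgeR adjusted p = 0.0545 and 0.0849).

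Among 20 macrophage and dendritic cell markers, 5 fell, 2 rose and 13 did not pass, with 8 and 3 adjusted over the list alone. Ccr2, a receptor gene of monocytes, fell 4.74-fold (edgeR adjusted p = 0.000324) and Cd209a fell 5.48-fold, while Cd14 and Cd163 rose 1.77-fold and 2.58-fold. The list was not called (median -0.11, camera adjusted p = 0.350), although it was without KO 3 (camera adjusted p = 0.0253). None of 9 T and natural killer cell markers passed, also adjusted over the list alone (median -0.23, camera adjusted p = 0.483). None of 4 B and plasma cell genes passed, with 2 higher adjusted over the list alone (median 0.38, camera adjusted p = 0.287), although fry called the list higher (adjusted p = 0.0185). Of 7 mast cell genes, the tryptase gene Tpsab1 rose and 6 did not pass, with 2 higher adjusted over the list alone. Tpsab1 had 3 wild-type and 55 knockout counts, a ratio of 10.96 (95% counting interval 3.56 to 54.8). The mast cell list was called higher (median 1.27, camera adjusted p = 0.0285), with adjusted p = 0.627 with an estimated correlation, and was not called without WT 2, KO 2 or KO 3 (camera adjusted p = 0.0912, 0.117 and 0.0549). Macrophage and dendritic genes that fell numbered 1 without WT 1, 2 without WT 2, 3 without KO 1 and 8 without KO 3. Without KO 1, 5 rose and the list median was 0.19. Cd209a (edgeR adjusted p = 0.0822), Cd163 (0.101) and Tpsab1 (0.232) did not pass without WT 1, nor did Cd163 (0.0984) and Tpsab1 (0.0995) without WT 2. With all libraries, Tpsab1 did not pass in limma-voom (adjusted p = 0.0673), where none of the 7 mast cell genes did, while 3 rose in DESeq2.

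Of 20 cytokine and mediator genes, 5 rose, 2 fell and 13 did not pass, with 6 and 3 adjusted over the list alone (median 0.01, camera adjusted p = 0.394). The chemokine genes Ccl6, Ccl9 and Cxcl14 rose 3.40-fold, 2.73-fold and 1.49-fold, and Cxcl12 fell 1.47-fold (edgeR adjusted p = 0.00354, 0.00549, 0.00374 and 0.00385). Of 16 NF-kappaB response genes, 5 rose, 1 fell (Vcam1, log2 fold change -0.65) and 10 did not pass, with 7 and 2 adjusted over the list alone. The adhesion molecule gene Icam1 rose 2.52-fold (edgeR adjusted p = 0.000863) and the regulators Nfkbiz and Bcl3 rose 2.16-fold and 1.94-fold. This list was called higher (median 0.21, camera adjusted p = 0.0152), with adjusted p = 0.545 with an estimated correlation. Without WT 1, the calls of Ccl6, Ccl9 and Cxcl12 were lost (edgeR adjusted p = 0.0631, 0.0872 and 0.0515), and 1 cytokine gene and 3 NF-kappaB genes rose. Without WT 2, the NF-kappaB list was not called (camera adjusted p = 0.0513), and Vcam1 did not pass without WT 1 or WT 2 (edgeR adjusted p = 0.0817 and 0.0984).

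Of 16 immediate early genes, 7 rose, none fell and 9 did not pass, with 7 higher and 1 lower adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signalling, rose 6.71-fold (edgeR adjusted p = 2.08e-05), the phosphatase gene Dusp1 rose 2.74-fold and Jun rose 1.61-fold, while Fos was at 37.0 ± 6.10 and 43.3 ± 5.83 CPM (edgeR adjusted p = 0.282). Immediate early genes were called higher as a list (median 0.22, camera adjusted p = 0.00123), with adjusted p = 0.501 with an estimated correlation. Of 17 heat shock and unfolded protein response genes, 8 rose, none fell and 9 did not pass, with 9 higher and 1 lower adjusted over the list alone. The chaperone genes Hspa1b, Calr and Hspa5 rose 2.36-fold, 1.83-fold and 1.57-fold (edgeR adjusted p = 0.000101, 0.000818 and 0.00281). This list was called higher (median 0.26, camera adjusted p = 5.17e-05), with adjusted p = 0.501 with an estimated correlation. Of 11 p53 target genes, Ccng1 rose 1.33-fold and 10 did not pass, with 1 adjusted over the list alone (median 0.02, camera adjusted p = 0.698). Without WT 1, 3 immediate early and 3 heat shock genes rose and the calls of Dusp1 (edgeR adjusted p = 0.0786) and Ccng1 (0.124) were lost, the latter also without WT 2 (0.125), KO 1 (0.0895) or KO 2 (0.0609). Without WT 2, 4 immediate early genes rose and their list was not called (camera adjusted p = 0.0510).

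Of 18 cholesterol synthesis genes, 8 rose, none fell and 10 did not pass, and adjusted over the list alone 10 were higher. Mvd, Fdps and Sqle, which encode enzymes of this pathway, rose 1.73-fold, 1.64-fold and 1.41-fold (edgeR adjusted p = 0.00158, 0.00233 and 0.00460). Camera called the cholesterol list higher (median 0.33, camera adjusted p = 0.000343), with adjusted p = 0.501 with an estimated correlation. Of 14 hypoxia and glycolysis genes, 4 rose and 10 did not pass, with 6 higher adjusted over the list alone. Ndrg1 rose 1.52-fold (edgeR adjusted p = 0.00252) and Adm rose 2.06-fold. This list was called higher (median 0.28, camera adjusted p = 0.0285), with adjusted p = 0.645 with an estimated correlation, and was not called without WT 1 or KO 2 (camera adjusted p = 0.0911 and 0.0868). Of 23 nuclear genes of oxidative phosphorylation, 3 rose (Ndufv1, Cox5a and Cox4i1) and 20 did not pass, and none passed adjusted over the list alone. Oxidative phosphorylation genes were called higher as a list (median 0.19, camera adjusted p = 0.0191), with adjusted p = 0.746 with an estimated correlation, and was not called without WT 1 or KO 2 (camera adjusted p = 0.544 and 0.0620). Its median was 0.01 without WT 1 and 0.37 without WT 2. Of 27 xenobiotic metabolism genes, 5 rose, 3 fell and 19 did not pass, with 6 and 3 adjusted over the list alone (median -0.01, camera adjusted p = 0.520). The cytochrome gene Cyp2f2 fell from 189 ± 14.1 CPM (SD, n = 2) to 11.1 ± 2.54 CPM (SD, n = 3; edgeR adjusted p = 7.44e-07) and the heme oxygenase gene Hmox1 rose 1.59-fold.

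Without WT 1, 3 cholesterol, 1 hypoxia, no oxidative phosphorylation and no xenobiotic genes rose, and Adm (edgeR adjusted p = 0.0583), Hmox1 (0.0740), Ndufv1 (0.195), Cox5a (0.302) and Cox4i1 (0.328) did not pass. Ndufv1, Cox5a and Cox4i1 did not pass without KO 1 (edgeR adjusted p = 0.103, 0.131 and 0.130) or KO 2 (0.120, 0.0895 and 0.137) either, nor Ndufv1 and Cox5a without WT 2 (0.0860 and 0.0630), and without WT 2, KO 1 or KO 2 the rising genes numbered 5, 8 and 7 for cholesterol, 3, 2 and 2 for hypoxia and 2, 3 and 2 for xenobiotic metabolism. With all libraries, no oxidative phosphorylation gene rose with upper-quartile scaling or a filter at 5 CPM, and 1 rose with library totals. Without KO 3, 7 hypoxia genes and 5 oxidative phosphorylation genes rose.

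Of 4 skeletal muscle genes, which mark tissue that dissection can carry along, Tnni2 rose 2.20-fold (edgeR adjusted p = 0.00311) and 3 did not pass, with 1 adjusted over the list alone, a median of -0.01, a mean of 0.19 and an upward test direction (camera adjusted p = 0.490). Of 11 nerve and Schwann cell genes, 3 rose and 8 did not pass, with 3 adjusted over the list alone. These were Uchl1, which rose 2.20-fold (edgeR adjusted p = 0.000371), the myelin gene Mbp, which rose 1.87-fold, and Ngfr, also a basal cell marker, and the list had a median of -0.09, a mean of 0.10 and an upward test direction (camera adjusted p = 0.353). None of 4 adipocyte genes passed, also adjusted over the list alone (median 0.10, camera adjusted p = 0.693). Of 2 mesothelial genes, Upk3b, also a uroplakin, rose 1.36-fold and Krt19 did not pass, with 2 higher adjusted over the list alone (median 0.39, camera adjusted p = 0.159). Tgm4, the 1 measured gene of accessory sex glands, had a log2 fold change of 0.22 (edgeR adjusted p = 0.493), did not pass adjusted over the list alone either and had camera adjusted p = 0.785. Alas2, the 1 measured erythroid gene, had a log2 fold change of 0.91 (edgeR adjusted p = 0.0875), was higher adjusted over the list alone and had camera adjusted p = 0.462. None of 5 sex-linked genes passed, also adjusted over the list alone (median -0.31, camera adjusted p = 0.385), and the Y-linked gene Ddx3y was at 82.1 ± 8.11 and 67.6 ± 9.70 CPM while Xist was at 1.07 ± 0.332 and 0.856 ± 0.279 CPM. Tnni2 (edgeR adjusted p = 0.0588) and Mbp (0.0889) did not pass without WT 1, Mbp (0.0984) not without WT 2, and Upk3b not without any of WT 1, WT 2, KO 1 and KO 2 (0.118, 0.0516, 0.0605 and 0.0505).

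The most strongly altered single genes were largely outside these lists, and many lay in the major histocompatibility complex on chromosome 17. The non-coding RNA Eyelinc18 rose from 0.671 ± 0.431 CPM (SD, n = 2) to 343 ± 24.4 CPM (SD, n = 3; edgeR adjusted p = 4.28e-08). Chil1, which encodes a chitinase-like protein, rose from 0.131 ± 0.111 to 50.4 ± 19.7 CPM, Eno1b rose 58.1-fold, and the membrane skeleton gene Dmtn rose 4.19-fold. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose from 22.3 ± 0.134 to 91.0 ± 8.64 CPM (edgeR adjusted p = 9.66e-06). Klk1b22, a kallikrein gene, had no wild-type count and 204 knockout counts, at least 40.6-fold higher against a floor of 3 counts over the wild-type group, but did not pass without WT 1 (edgeR adjusted p = 0.0635). The Klk1b22 values were 2.258, 2.045 and 8.565 CPM in KO 1, KO 2 and KO 3, so its bound leans on KO 3. Ifi202b had 1 wild-type count and a ratio of 148 (95% counting interval 26.4 to 5878). Ifi202b and Cfap126, given below, lie on chromosome 1 within 10 Mb of Ncstn. Changes over 4-fold were more frequent there than elsewhere, as described in the closing section, so strain variants beside Ncstn remain possible for both. Among genes that fell, Pttg1, which encodes securin, a regulator of chromosome separation, went from 41.6 ± 4.76 to 2.04 ± 0.535 CPM (edgeR adjusted p = 1.49e-06). Cyp2e1 fell 19.4-fold, Slc15a2 fell 19.4-fold, Cfap126 fell 17.3-fold, Ndp, which encodes a secreted ligand of Wnt receptors, fell 36.1-fold, Fut2 fell 13.1-fold and the unnamed transcript E130008D07Rik fell 42.1-fold. Slc15a2 was at 0.452, 0.301 and 2.96 CPM in KO 1, KO 2 and KO 3, so its fold depends strongly on KO 3.

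Within the histocompatibility complex, changes of opposite sign lay side by side. H2-T10 (chromosome 17, 36115876 to 36121465, GRCm38) rose from 4.51 ± 0.0275 CPM (SD, n = 2) to 56.6 ± 0.471 CPM (SD, n = 3; edgeR adjusted p = 2.79e-07). H2-T23 (36029773 to 36032855) fell from 216 ± 26.2 to 17.1 ± 5.21 CPM (edgeR adjusted p = 5.48e-06), and H2-Q5 (35394126 to 35397800) fell 13.8-fold. H2-T3 (36185572 to 36190287) had 1 wild-type and 546 knockout counts, a ratio of 326 (95% counting interval 58.3 to 12913). H2-Bl (36080115 to 36084223) had 2 and 629 counts, a ratio of 188 (95% counting interval 51.8 to 1556). H2-Eb1 lies at 34305867 to 34316674 on the same chromosome. Of 123 tested genes between 33974659 and 37274484, 18 (14.6%) changed over 4-fold, 12 up and 6 down, against 1.58% elsewhere. The H2-T, H2-Q and Klk1b genes belong to families of near-identical copies, and Eno1b is a close copy of Eno1, so reads may be shared between copies. Single-gene values there are therefore uncertain.

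**Figure D3:**
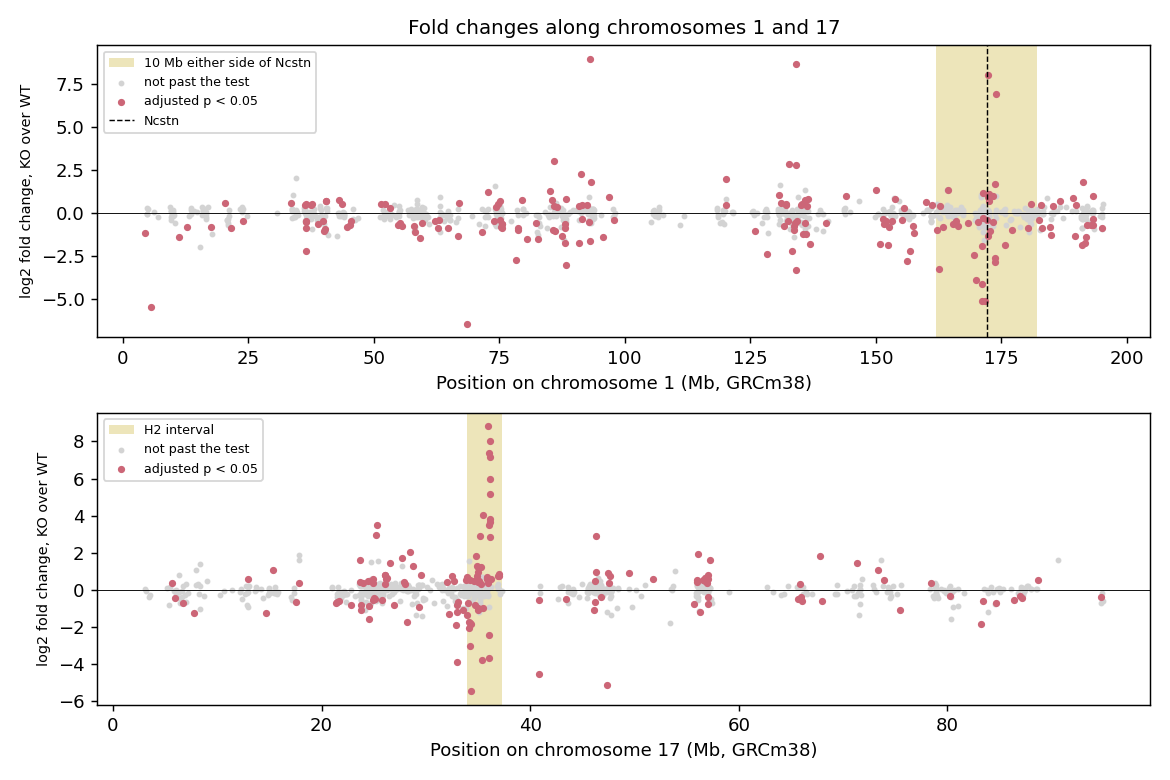
Log2 fold change, knockout over wild type (y axis), of each tested gene against its position in Mb (x axis, GRCm38) on chromosome 1 with the 10 Mb on either side of Ncstn shaded and on chromosome 17 with the histocompatibility interval shaded. Genes past the edgeR test are red, and the shaded interval of chromosome 17 holds 18 changes over 4-fold in both directions.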

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

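Apart from the tests of all changed genes near Ncstn and Krt5, which were fixed beforehand, the tests below were chosen after the results were seen.

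Ncstn differed little between genotypes, with a log2 fold change of -0.21 (edgeR adjusted p = 0.133), in mice labelled as knockouts. The values argue against a library swapped between the groups. The lowest Spearman correlation within a genotype exceeded the highest between genotypes by 0.00852, and the values of Hey1 and Heyl did not overlap. They do not check the Ncstn genotype of each library, since the groups may also differ in background and differ in their share of Rn45s. Reads from undeleted exons and from cells outside the Krt5 lineage could account for the value of -0.21, which was not tested further because the counts are not split by exon. A low rate of recombination remains open for the same reason. That Notch signalling was reduced in the recombined cells remains an untested hypothesis, because Hey1 and Heyl are low in level and also expressed in vessels, whose markers Kdr and Sox17 fell 2.40-fold and 2.22-fold, and Hes1 did not pass.

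Very large changes clustered in the histocompatibility complex and beside Ncstn. The tests of changes over 4-fold were prompted by this clustering, so their p values describe it and are not independent evidence of a cause. Near Ncstn, 10 of 160 genes within 10 Mb changed over 4-fold (6.25% against 1.64% elsewhere, odds ratio 4.01, 95% interval 1.86 to 7.71, Fisher's exact test p = 0.000387; p = 3.18e-05 to 0.00997 with single libraries left out), which is consistent with strain variants carried along with the floxed allele, although the test of all changed genes gave no excess past the threshold near Ncstn (p = 0.369) or Krt5 (p = 0.672). In the histocompatibility interval 18 of 123 genes changed over 4-fold (odds ratio 10.7, 95% interval 6.00 to 18.1, Fisher's exact test p = 2.38e-12; p = 5.61e-14 to 1.54e-11 with single libraries left out), consistent with another H2 haplotype in the knockouts, whose labels name no strain while the wild types are C57Bl/6. Fewer antigen-presenting cells were excluded as the entire cause for H2-Eb1, since its log2 ratio to H2-Aa plus H2-Ab1 was lower by 3.37 (-3.37, larger SD 0.636) in the knockouts, and reads moved between near-identical copies remain open with a log2 difference of -0.67 (SD 0.34) in their sum. The genotypes may therefore differ in background as well as in Ncstn, which sequence variants in the reads would test. Any gene here could owe its change to background, to Ncstn or to other differences between the libraries, such as their share of Rn45s.

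Of 31 fibrillar matrix genes and 18 fibroblast markers, 25 and 12 fell in the knockouts (edgeR). Neither list call held with an estimated correlation, a setting of little power here in which no called list held. Of 18 fibroblast markers, 11 lay more than 2 SE from their list median of -0.56, so they did not fall by a common factor. That median lay 0.51 below that of smooth muscle (permutation p = 0.0249, 100000 resamples, with genes treated as independent). Neither value excludes a smaller share of stroma in the dissected tissue as the entire cause, since kinds of fibroblast and muscle can vary separately. A smaller share would also raise epithelial lists such as the umbrella cell list (median 0.42). Ribosomal and nuclear RNA content remains open, because between KO 1 and KO 3, the knockouts with the most and least Rn45s, the matrix mean differed by -0.24 log2 CPM, against 0.17 between WT 1 and WT 2 and -0.90 between genotypes. Leaving out the ribosomal and nuclear RNA entries kept the matrix median at -0.87 with 25 of 31 genes lower. That speaks only to the weight of these entries in the scaling. Transcript length and GC content did not account for most of the fall, as the list median stayed at -0.73 (SE 0.16) after correction against -0.86 before. That SE treats genes as independent and leaves out differences between mice. A response of stroma to signals from Ncstn-deficient epithelium remains an untested hypothesis.

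The share of tallied reads that was ambiguous was 1.147% in KO 1, 1.092% in KO 2 and 1.137% in KO 3 against at most 1.089% in the wild types, the share not aligned was 9.431% in KO 2 against at most 7.657%, and the share not uniquely aligned was 25.84% in KO 1 against at most 25.10%. Shares also lay below both wild types. Reads in no gene made up 17.1% and 13.3% in the wild types and 11.5%, 9.79% and 11.3% in KO 1, KO 2 and KO 3, the share not aligned was 5.30% in KO 1 and 4.61% in KO 3 against at least 6.37%, and the share not uniquely aligned was 23.4% in KO 2 and 22.3% in KO 3 against at least 24.3%. The cause of these differences was not tested.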

How the results depend on the processing

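The first analysis called 2907 genes (1424 higher, 1483 lower), 4637 were called with a replicate block (2211 higher, 2426 lower), and leaving out 1 library gave 715 without WT 1, 1429 without WT 2, 1747 without KO 1, 1901 without KO 2 and 3989 without KO 3 (340 to 1743 higher, 375 to 2246 lower). Replicate number 3 occurs only in the knockouts, so in the block fit KO 3 does not inform the genotype comparison. Replicate numbers were not taken to pair the samples. Across genes, deviations from the genotype mean correlated at r = -0.055 for WT 1 with KO 1 and 0.052 for WT 2 with KO 2, with only 2 pairs. The deviations of 2 wild types are mirror images (r = 0.055 for WT 2 with KO 1), so these values cannot show whether samples were paired. A wild type left alone was assumed to vary like the knockouts. Other settings gave 2389 (stricter filter), 3859 (no filter), 2729 (library totals), 2878 (upper quartile, 40.5% higher against 49.0%), 2906 (median of ratios), 2972 (robust), 2902 (DESeq2) and 3120 (limma-voom). Without ribosomal and nuclear RNA entries, chosen after seeing the data, 2904 changed (1361 higher, 1543 lower). No call of the first analysis changed sign. Of 141 named genes called, 54 were lost without WT 1, 25 without WT 2, 16 without KO 1, 15 without KO 2 and 0 without KO 3, and over all settings 2757 of 2967 named gene results kept their label, 128 were weaker, 82 stronger and 0 reversed. Of 201 named genes, those not called changed sign in 26 combinations of gene and setting, so a gene can count more than once. Of the 20 called lists, 0 held with an estimated correlation and 9 with fry, which also called 2 others (11 in all), while at the preset correlation, over 13 other settings, 13 of 556 list results lost a call, 8 gained one and 535 did neither. The cause was not tested, and the losses with an estimated correlation do not show that correlated genes produced the calls.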

Other observations

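Unless stated otherwise, the genes in this part were chosen after their values were seen. Several acute phase and defence genes were among the changed genes. Reg3g, an antibacterial lectin gene, rose from 2.81 ± 0.823 CPM (SD, n = 2) to 36.5 ± 8.46 CPM (SD, n = 3; edgeR adjusted p = 2.08e-05), Serpina3n, an acute phase protease inhibitor gene, from 426 ± 4.57 to 1766 ± 906 CPM (edgeR adjusted p = 0.00655), and Saa3 by 4.80 on the log2 scale. The transcription factor gene Cebpd rose from 10.5 ± 1.19 to 40.1 ± 1.83 CPM and Stat3, which carries cytokine signals to the nucleus, by 0.60 on the log2 scale. Of 15 such genes 13 rose and none fell, and as the list was drawn up from these samples it is not independent evidence of its direction.

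Of 16 targets of the glucocorticoid receptor, a list also drawn up from these samples, 11 rose and none fell. Tsc22d3 rose from 46.8 ± 1.66 to 132 ± 6.30 CPM (edgeR adjusted p = 1.77e-05) and Zbtb16 rose 18.4-fold to 28.3 ± 8.46 CPM (edgeR adjusted p = 3.36e-05), beside Fkbp5. Of 4 genes of EGF receptor ligands looked at, with no list test, Areg rose from 0.984 ± 0.307 to 5.83 ± 0.980 CPM (edgeR adjusted p = 0.000590), Ereg by 3.64 on the log2 scale and Hbegf 2.39-fold, while Tgfa had a log2 fold change of 0.20 (edgeR adjusted p = 0.191).

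The hypothesis that a glucocorticoid response extends to other targets was tested on a list of genes not looked at before. Of 19 measured, 8 rose, among them Glul and Map3k6, and 1, Arrdc3, fell. The median log2 fold change was 0.10, and limma camera gave adjusted p = 0.0495 over the 2 lists tested (0.0248 before adjustment). Adjusted over the same 2 lists, the call was lost without WT 2 (adjusted p = 0.0711), KO 2 (adjusted p = 0.0513) and KO 3 (adjusted p = 0.134) and held without WT 1 (adjusted p = 0.0452) and KO 1 (adjusted p = 0.0324), and the unadjusted value was 0.0926 with an estimated correlation. A wider glucocorticoid response, which differences in stress or handling between mice could also cause, therefore remains an unsettled hypothesis at a value of 0.0248.

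The rise of Ctgf and Cyr61 raised the hypothesis of YAP and TEAD activity, since both are targets of these factors. In a list of other targets written beforehand, 4 of 18 rose and 3 fell. The median was 0.05, and limma camera gave adjusted p = 0.501, with adjusted p = 0.178 to 0.901 when single libraries were left out. This test cannot tell whether the pathway was active, and the rise of Ctgf and Cyr61 may have another cause.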
